A study of Homo sapiens with 6 samples.

How the data were processed

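RNA of 6 samples was measured, 2 each of NCC aggregates at day 5, mdEM at day 9 and clusters at day 38, all from the 1231A3 line. Per the labels' protocols, RNA was extracted with a column kit, 10 ng was amplified in 13 PCR cycles with an Ion AmpliSeq panel covering the human transcriptome, and the amplicons were sequenced. The submitters' processing notes name the hg19 genome and DESeq2, without versions; the aligner and the counting program are not given in the sources used here. The deposited values, per the labels, are counts of reads for each gene and sample, and they were used as counts. The table held 20812 lines, of which 10 were spike-in controls with 0 counts in all samples. Of the 20802 gene lines, 28 carried a date in place of a symbol; they held 0.281% of the counts, were kept in totals and tests, and are never named. All samples had 0 counts for 2357 genes.

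Symbols were matched to current and earlier names in RefSeq GRCh38.p14, with 19904 of 20802 gene lines matched. Loci are from GENCODE 29 on GRCh38; they place genes and not amplicons, and they are not on the build named by the submitters. Totals lay between 10612691 and 11406967 counts, at which 3 counts were worth 0.245 to 0.313 CPM. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), leaving 13991. Library sizes were normalised by TMM (factors 0.894 to 1.08), and CPM (counts scaled to a common library size in edgeR's cpm) are on that scale.

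Groups followed the labels, and 3 comparisons were made, day 9 against day 5, day 38 against day 9 and day 38 against day 5. All 6 libraries entered 1 fit in edgeR 4.0.16 (R 4.3.3) with 3 residual degrees of freedom, estimateDisp, glmQLFit with robust=TRUE and legacy=TRUE, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Standard errors were taken from the fold change and the F statistic. A gene with 0 counts in the lower group is given as a lower bound on its fold from 3 counts over the group, and 1 with 1 to 3 counts as a ratio with a 95% counting interval. Lists of genes, 32 in number, were fixed before the data were examined; the 29 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 between genes, adjusted over the lists. The same test with the correlation estimated from the residuals is printed beside each call. Genes within a list were also adjusted over the list alone. Some genes are in more than 1 list, such as COL1A1 in the osteoblast and collagen lists, so results of such lists are not independent.

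The genes to name were chosen by a rule written before the data were examined. Among genes past the threshold with a mean of at least 20 CPM in the higher group and no overlap between libraries of the groups, the rule took the 8 largest rises and the 8 largest falls of each comparison, up to 3 genes per list, and 6 each of those highest and lowest at day 9; 37 marker genes were named whatever their result. The text uses fewer for space. A gene was counted as highest or lowest at day 9 when it passed the threshold at both steps with at least a 2-fold change at each.

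The method was tested on simulated data with 200 changed genes per set, 5 sets per comparison. It recovered 35.2, 32.4 and 31.6% of 2-fold changes and 86.8, 83.4 and 84% of 4-fold changes for the 3 comparisons in the order above. False calls were 56 of 666 (8.41%), 47 of 626 (7.51%) and 41 of 619 (6.62%), above the nominal 5%. The number of sets was raised from 1 to 5 after the first result was seen. Each set changed 200 of 13991 genes, a far smaller share than was called in the data, so these rates need not hold there. In 1 draw per comparison with 1 raised list, that list had an adjusted p of 2.13e-19, 4.01e-21 and 6.77e-24 with 0 false lists, and 0.0795, 0.0508 and 0.0423 with an estimated correlation. The simulated genes were drawn independently and the lists at random. The 0 false lists therefore do not test the preset correlation on lists of correlated genes.

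Alternatives fixed before the data were examined were the DESeq2 1.42.0 Wald test, limma-voom, RLE and upper-quartile factors, no low-count filter, a filter of 5 CPM in 2 libraries, fits of only the groups compared, a replicate block, legacy=FALSE, scaling without the 100 most abundant genes, each library left out in turn, and for lists the estimated correlation, fry, RLE factors, the replicate block and no filter. A replicate block with the day 9 numbers exchanged was added after the data were seen. Groups of 2 do not allow an outlier rule or a regrouping of samples, and none was applied. Figures were drawn with matplotlib 3.10.9. Read-level data were not used here.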

Results

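Gene expression was measured at 3 stages of a culture that began from 1231A3, an established human induced pluripotent stem cell line. The stages were neural crest cell (NCC) aggregates at day 5, mandibular prominence ectomesenchyme (mdEM) at day 9 and clusters at day 38, with 2 libraries each. Neural crest cells are embryonic migratory cells that form much of the facial skeleton, and ectomesenchyme is the mesenchyme they give rise to. From day 5 to day 9 the aggregates received the growth factors FGF8b at 100 ng/ml and BMP4 at 2.5 ng/ml and the peptide endothelin-1 at 50 nM. The mdEM were next held for 3 days in EGF and FGF at 20 ng/ml, BMP2 at 50 ng/ml, the GSK-3 inhibitor CHIR99021 at 3 µM and the Smoothened agonist SAG at 400 nM. A commercial osteogenic medium followed from day 12, a medium with β-glycerophosphate, ascorbate, 100 nM dexamethasone, BMP2, CHIR99021 and SAG from day 19, and the commercial medium again from day 26 to day 38. Each library came from 10 ng of RNA and a multiplex amplicon panel that reads a short stretch of each transcript, so levels of different genes also depend on their primers.

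The 6 libraries held between 10612691 and 11406967 counts, and between 15504 and 16529 genes had at least 1 count. The 10 most abundant genes of each library took 6.89 to 8.37% of the counts at day 5 and day 9, and 20.8 and 21.0% at day 38. COL1A1 and COL1A2, which encode the chains of type I collagen, alone took 11.5 and 11.4% of the counts of the day 38 libraries. Replicates correlated across genes with r = 0.981 at day 5, 0.973 at day 9 and 0.989 at day 38, while libraries of different stages correlated at 0.739 to 0.902; genes are not independent replicates in these values. The chi-square per gene between replicates was 30.7, 36.5 and 5.59; it treats PCR reads as independent molecules, so a value over 1 does not by itself show a difference between the samples. A gene with 0 counts in a library is limited by 3 counts, which were worth 0.245 to 0.313 CPM, the normalised unit used throughout. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Values are mean ± SD, n = 2, in CPM; adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13991 genes, and those of gene lists are from camera.

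The first comparison covers the induction of mdEM. Between day 5 and day 9, 13 of 18 neural crest genes fell, and 10 of 14 genes of mandibular patterning rose. SOX10, a transcription factor of neural crest and its glial derivatives, fell from 586 ± 146 to 28.5 ± 3.76 CPM (adjusted p = 6.93e-06). TWIST1, a mesenchymal transcription factor, rose from 5.64 ± 1.04 to 398 ± 147 CPM (adjusted p = 4.09e-06). BARX1, a transcription factor of oral and molar-region mesenchyme, had 0 counts at day 5 and 150 ± 12.7 CPM at day 9, at least 1171-fold higher against a floor of 3 counts over the group (adjusted p = 2.77e-06). Of the 13991 genes tested, 3323 (23.8%) changed, 1991 upward and 1332 downward, and 1632 and 912 of these changed at least 2-fold. The spread in this fit was estimated with the day 38 libraries as well, and a fit of only the 2 groups compared called 2405 genes.

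The neural crest list had 13 of its 18 tested genes lower, 0 higher and 5 not past the test, the same 13 adjusted over the list alone, with a median log2 fold change of -2.04 (adjusted p = 3.33e-08, adjusted p = 0.14 with an estimated correlation). TFAP2B, a crest transcription factor, fell from 514 ± 33.7 to 82.5 ± 14.6 CPM (adjusted p = 2.31e-05). PAX3, which marks the neural plate border and crest, fell from 320 ± 18.4 to 81.5 ± 0.962 CPM (adjusted p = 6.05e-05). FOXD3, a regulator of early crest, fell from 138 ± 13.6 to 0.929 ± 0.958 CPM, a log2 fold change of -7.20 (adjusted p = 1.37e-05) that was -6.41 without mdEM day 9 replicate 2. The adjusted p was 8.19e-07 without mdEM day 9 replicate 1, which left 3 counts. The nerve growth factor receptor gene NGFR fell from 155 ± 85.3 to 6.60 ± 5.75 CPM, a log2 fold change of -4.55 (adjusted p = 0.000458); it was -3.85 without NCC aggregates day 5 replicate 1, -3.86 without mdEM day 9 replicate 1 and -5.92 without mdEM day 9 replicate 2. TFAP2A stood at 395 ± 34.4 and 287 ± 56.2 CPM (adjusted p = 0.135) and SNAI2, a gene of migrating crest, at 111 ± 6.23 and 132 ± 21.5 CPM (adjusted p = 0.393), so neither differed by more than the spread allowed for. SOX9, shared by crest and cartilage, was at 50.8 ± 29.6 and 71.4 ± 20.9 CPM (adjusted p = 0.378, but 0.029 without NCC aggregates day 5 replicate 1).

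Ectomesenchyme genes moved the other way: 14 of 18 rose, 1 fell and 3 did not pass, as also adjusted over the list alone, with a median of 3.61 (adjusted p = 7.03e-09, adjusted p = 0.19 with an estimated correlation). DLX1 and DLX2, homeobox genes of the pharyngeal arches, rose from 6.76 ± 2.00 to 182 ± 26.5 CPM (adjusted p = 4.25e-06) and from 42.8 ± 11.9 to 183 ± 23.5 CPM (adjusted p = 0.000235). FLI1, an ETS transcription factor, rose from 0.509 ± 0.0894 to 97.9 ± 18.8 CPM (adjusted p = 2.06e-06). MSX1, a BMP-responsive homeobox gene of jaw and tooth mesenchyme, rose to 54.6 ± 14.4 CPM, a log2 fold change of 2.32 (adjusted p = 0.000155). PRRX1, a limb and face mesenchyme gene, went from 1 count to 16.7 ± 10.5 CPM, a ratio of 391 with a counting interval of 69.8 to 15500 (adjusted p = 0.000104). Its adjusted p was 0.00264 without NCC aggregates day 5 replicate 1, 0.00406 without NCC aggregates day 5 replicate 2 and 1.89e-05 without mdEM day 9 replicate 2. PRRX1 had 109 and 287 counts in mdEM day 9 replicates 1 and 2, a spread that the counting interval does not cover. The member that fell was EDNRA, the endothelin receptor gene through which the arch mesenchyme takes its lower jaw identity, from 808 ± 212 to 188 ± 38.8 CPM (adjusted p = 0.000235).

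Genes of mandibular patterning rose in 10 of 14 cases, 1 fell and 3 did not pass; adjusted over the list alone 11 rose and 2 fell. The median was 4.53, or 4.47 with genes at their bounds (adjusted p = 1.43e-05, adjusted p = 0.2 with an estimated correlation). GSC, a homeobox gene of the lower jaw, rose from 0.171 ± 0.0105 to 45.5 ± 20.1 CPM (adjusted p = 8.1e-06). DLX5, which with DLX6 specifies that jaw, rose from 7.36 ± 3.47 to 167 ± 48.3 CPM (adjusted p = 2.24e-05). DLX6 rose from 0.532 ± 0.752 to 119 ± 31.0 CPM, a log2 fold change of 7.73 (adjusted p = 2.42e-05) that was 6.78 without NCC aggregates day 5 replicate 2, while without NCC aggregates day 5 replicate 1 the adjusted p was 0.000145. HAND2, the effector of endothelin signalling in the ventral arch, had 1 count over the day 5 libraries and 473 ± 125 CPM at day 9, a ratio of 11100 with a counting interval of 1990 to 438000 (adjusted p = 1.34e-06). The adjusted p of HAND2 was 0.000127 without NCC aggregates day 5 replicate 1 and 0.000182 without NCC aggregates day 5 replicate 2. HAND2 lies on chromosome 4 at 173524969 to 173530229 (GRCh38, GENCODE 29), and the antisense gene HAND2-AS1, listed as NBLA00301, spans 173527270 to 173659696. It went from 0 counts to 116 ± 40.0 CPM, at least 911-fold higher (adjusted p = 4.25e-06). Only part of its span overlaps HAND2, and where its amplicon lies is not known. Reads from the shared stretch could not be told apart without strand. HAND1 was at 0.576 ± 0.689 and 0.0843 ± 0.000361 CPM (adjusted p = 0.128, but 0.0221 without NCC aggregates day 5 replicate 2).

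The maxillary and frontonasal list, fixed as the counterpart to the mandibular one, also rose, with 7 genes higher, 1 lower and 4 not past the test, as adjusted over the list alone, and a median of 2.29 (adjusted p = 0.000736, adjusted p = 0.14 with an estimated correlation). MEIS2, a homeobox cofactor of cranial crest, rose from 47.4 ± 2.18 to 265 ± 32.3 CPM (adjusted p = 2.15e-05). ALX1, a frontonasal homeobox gene, rose from 14.5 ± 1.71 to 33.4 ± 1.53 CPM (adjusted p = 0.00277). The 38 HOX genes measured, some of which mark crest behind the first arch, summed to 0.535 CPM at day 5, 1.26 CPM at day 9 and 8.05 CPM at day 38. Too few passed the count filter for a test of the list. The 2 that passed it were both called higher at day 38 than at day 9 and than at day 5. The highest of the 38 was HOXA13 at 3.00 CPM at day 38, named after its value was seen.

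**Figure D1:**
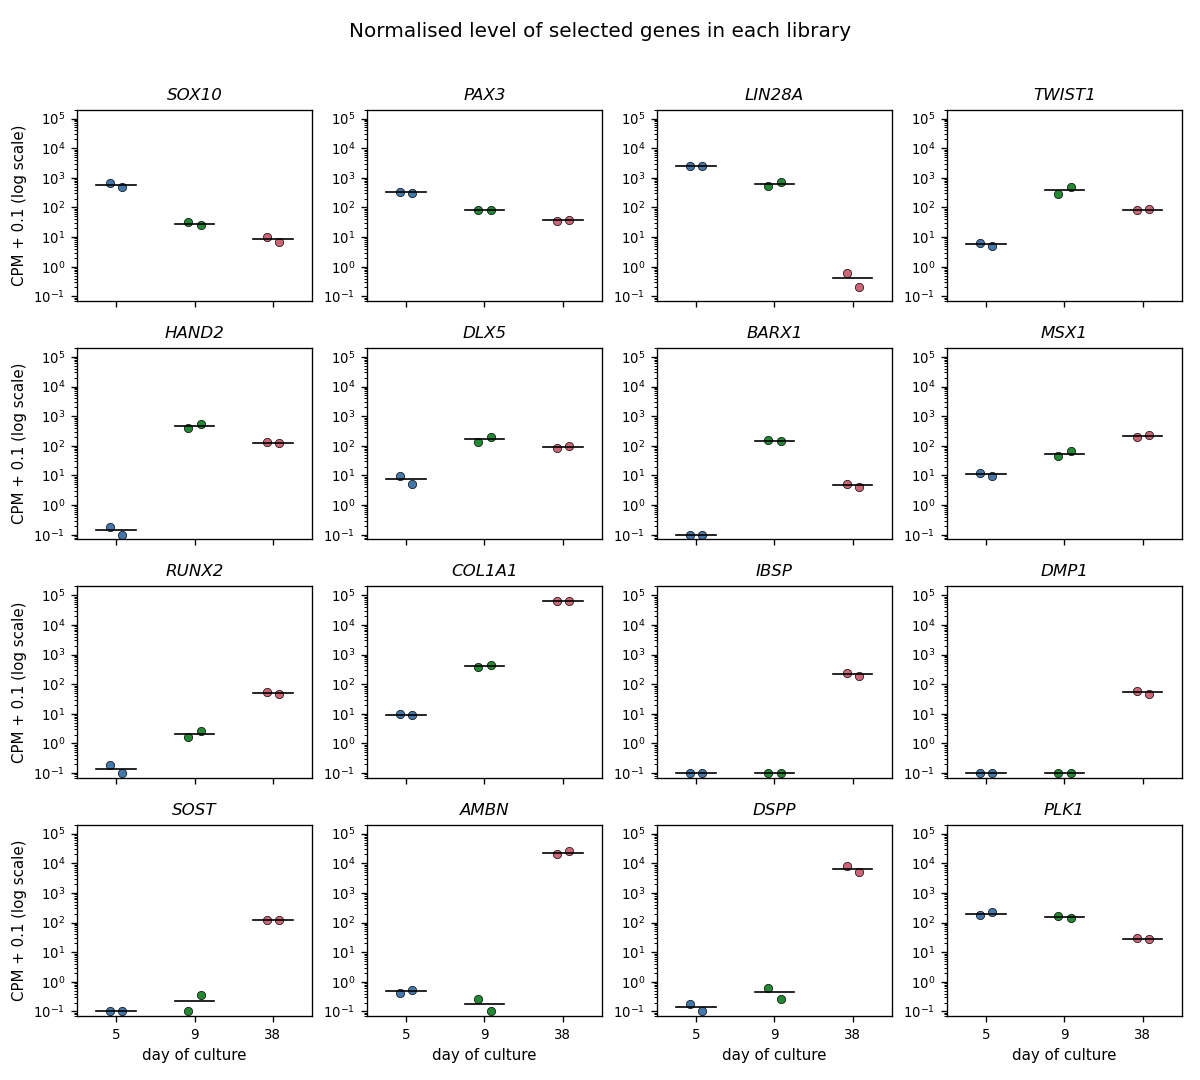
Normalised level of 16 genes in each of the 6 libraries, as CPM + 0.1 on a log axis against day of culture; points are libraries and lines are means of 2. SOX10 fell from 586 CPM at day 5 to 8.24 CPM at day 38, HAND2 and BARX1 were highest at day 9, and COL1A1 reached 63640 CPM at day 38.

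Response genes of signalling pathways were tested as lists, and of these pathways FGF and BMP had ligands added in this step. FGF response genes rose in 10 of 13 cases, 1 fell and 2 did not pass (11 and 1 adjusted over the list alone, median 2.31, adjusted p = 5.8e-07, adjusted p = 0.14 with an estimated correlation). DUSP6, a phosphatase that restrains ERK, rose from 6.36 ± 1.48 to 165 ± 31.1 CPM (adjusted p = 4.29e-06). SPRY2, another ERK pathway inhibitor, rose from 18.1 ± 3.42 to 172 ± 27.2 CPM (adjusted p = 1.24e-05). Of 16 BMP response genes, 9 rose, 2 fell and 5 did not pass (10 and 2 adjusted over the list alone, median 1.70, adjusted p = 0.00687, adjusted p = 0.559 with an estimated correlation), and the list's adjusted p was 0.056 with fry. WNT response genes fell in 8 of 14 cases, 2 rose and 4 did not pass (the same adjusted over the list alone, median -1.06, adjusted p = 0.00228, adjusted p = 0.14 with an estimated correlation). NKD1, a feedback inhibitor of WNT signalling, fell from 193 ± 79.7 to 16.5 ± 4.24 CPM (adjusted p = 5.82e-05). The hedgehog response list, with 2 of 11 genes higher and 1 lower, did not pass (adjusted p = 0.807), and its counts moved by more than 1.5 times when single libraries were left out.

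Neural progenitor genes fell in 12 of 13 cases with 0 higher (13 and 0 adjusted over the list alone, median -3.34, adjusted p = 5.68e-09, adjusted p = 0.14 with an estimated correlation). SOX2, shared by pluripotent and neural stem cells, fell from 92.4 ± 35.0 to 2.49 ± 0.309 CPM (adjusted p = 8.41e-06). ZIC2, a neural plate zinc finger gene, fell from 40.0 ± 9.67 to 2.57 ± 0.309 CPM (adjusted p = 2.04e-05). Schwann cell and glia genes fell in 7 of 10 cases with 0 higher, also adjusted over the list alone (median -3.07, adjusted p = 0.000129, adjusted p = 0.255 with an estimated correlation). S100B, a glial calcium-binding protein gene, fell from 93.0 ± 3.77 to 1.18 ± 0.601 CPM, a log2 fold change of -6.29 (adjusted p = 4.01e-06) that was -6.92 without mdEM day 9 replicate 1. Pluripotency genes fell in 7 of 12 cases with 0 higher (7 and 1 adjusted over the list alone, median -1.19, adjusted p = 0.000736, adjusted p = 0.295 with an estimated correlation), and in 4 without NCC aggregates day 5 replicate 1. LIN28A, an RNA-binding protein gene that blocks let-7 maturation, fell from 2481 ± 88.2 to 610 ± 124 CPM (adjusted p = 0.000307). POU5F1, for which near-identical pseudogenes leave reads uncertain, fell from 6.34 ± 0.992 to 0.631 ± 0.534 CPM, a log2 fold change of -3.30 (adjusted p = 0.00321) that was -2.64 without mdEM day 9 replicate 1. Without mdEM day 9 replicate 2, which left 3 counts, the adjusted p was 0.000917.

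Collagen assembly and crosslinking genes rose in 18 of 28 cases, 1 fell and 9 did not pass (20 and 1 adjusted over the list alone, median 1.69, adjusted p = 2.11e-07, adjusted p = 0.14 with an estimated correlation). COL1A1 rose from 9.21 ± 0.281 to 405 ± 54.9 CPM (adjusted p = 1.34e-06). In the osteoblast list 7 of 21 genes rose and 2 fell, also adjusted over the list alone (median 0.34, adjusted p = 0.0323, adjusted p = 0.191 with an estimated correlation); its adjusted p was 0.0552 without NCC aggregates day 5 replicate 2 and 0.0559 without mdEM day 9 replicate 1. PTH1R, the parathyroid hormone receptor gene, rose from 0.253 ± 0.105 to 90.8 ± 28.9 CPM (adjusted p = 2.79e-06), while ALPL, the mineralisation phosphatase gene, fell from 13.1 ± 5.71 to 1.60 ± 0.484 CPM (adjusted p = 0.000331). Dental mesenchyme and odontoblast genes rose in 6 of 13 cases and 1 fell (7 and 1 adjusted over the list alone, median 2.32, or 2.25 with genes at their bounds, adjusted p = 0.00162, adjusted p = 0.14 with an estimated correlation). Osteocyte, chondrocyte and tendon lists did not pass (adjusted p = 0.807, 0.345 and 0.667), although COL2A1, the main cartilage collagen gene, rose from 151 ± 19.4 to 654 ± 35.6 CPM (adjusted p = 5.9e-05).

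Cell cycle genes fell in 7 of 24 cases with 0 higher, also adjusted over the list alone (median -0.40, adjusted p = 0.000736, adjusted p = 0.398 with an estimated correlation). The number lower was 3 without NCC aggregates day 5 replicate 2 and 4 without mdEM day 9 replicate 2 or either day 38 library, and the list's adjusted p was 0.0656 with fry. RRM2, a ribonucleotide reductase subunit gene, fell from 287 ± 93.1 to 118 ± 26.2 CPM (adjusted p = 0.0054). Glucocorticoid response genes rose in 7 of 13 cases with 0 lower, also adjusted over the list alone (median 0.87, adjusted p = 0.0212, adjusted p = 0.19 with an estimated correlation). Without NCC aggregates day 5 replicate 1 the number was 3 and the adjusted p of the list 0.0859, and without NCC aggregates day 5 replicate 2 or either day 38 library the number was 4. TSC22D3, a glucocorticoid-induced leucine zipper gene, rose from 36.2 ± 2.91 to 224 ± 10.3 CPM (adjusted p = 2.49e-05). Hypoxia, integrated stress and ribosomal protein lists did not pass (adjusted p = 0.532, 0.63 and 0.807).

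Among the largest changes outside these lists, the transcription factor gene MECOM and the actin-associated SYNPO had 0 counts at day 5 and 20.5 ± 6.41 and 38.9 ± 6.43 CPM at day 9, at least 160- and 304-fold higher (adjusted p = 8.67e-05 and 4.81e-06). PRDM12, a regulator of sensory neuron development, fell from 53.8 ± 20.7 to 0.380 ± 0.419 CPM, a log2 fold change of -7.11 (adjusted p = 2.2e-05) that was -6.29 without mdEM day 9 replicate 2. The adjusted p was 6.37e-06 without mdEM day 9 replicate 1, which left 1 count. Neuron genes fell in 8 of 18 cases and 2 rose (9 and 2 adjusted over the list alone, median -1.06, adjusted p = 0.0372, adjusted p = 0.602 with an estimated correlation), and 5 fell without NCC aggregates day 5 replicate 1 or 2. The neuron list's adjusted p was 0.0904 without NCC aggregates day 5 replicate 1, 0.248 without mdEM day 9 replicate 2, 0.0509 and 0.0508 without day 38 replicates 1 and 2, 0.0627 without the low-count filter and 0.274 with fry. DCX, a microtubule protein gene of young neurons, was the exception among its named members and rose from 42.4 ± 0.902 to 180 ± 65.0 CPM (adjusted p = 0.000324).

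The second comparison covers the osteogenic culture of mdEM. Between day 9 and day 38, 18 of 21 osteoblast genes rose, and 23 of 24 cell cycle genes and 9 of 12 pluripotency genes fell. COL1A1 rose 157-fold, from 405 ± 54.9 to 63640 ± 787 CPM (adjusted p = 1.09e-07). IBSP, the bone sialoprotein gene, had 0 counts at day 9 and 217 ± 28.8 CPM at day 38, at least 1709-fold higher (adjusted p = 1.13e-06). PLK1, a mitotic kinase gene, fell from 153 ± 15.8 to 28.3 ± 0.805 CPM (adjusted p = 1.77e-05). In this step 5756 genes (41.1%) changed, 3084 upward and 2672 downward, and 2481 and 1574 of these changed at least 2-fold. With a single day 38 library fewer genes changed: 3160 without replicate 1 (2021 higher and 1139 lower) and 3019 without replicate 2 (1959 higher and 1060 lower).

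Osteoblast genes rose in 18 of 21 cases, 2 fell and 1 did not pass (19 and 2 adjusted over the list alone), with a median log2 fold change of 4.97 (adjusted p = 4.71e-10, adjusted p = 0.0737 with an estimated correlation). RUNX2, the transcription factor gene required for osteoblast formation, rose from 2.02 ± 0.706 to 52.1 ± 5.28 CPM (adjusted p = 6.51e-06). ALPL rose from 1.60 ± 0.484 to 211 ± 18.3 CPM (adjusted p = 1.4e-06). SPARC, the osteonectin gene, rose from 492 ± 29.2 to 15460 ± 230 CPM (adjusted p = 3.65e-07). OMD, a bone proteoglycan gene, rose from 0 counts to 113 ± 5.37 CPM, at least 895-fold higher (adjusted p = 1.46e-06). SP7, the osteoblast zinc finger gene downstream of RUNX2, went from 1 count to 36.5 ± 3.67 CPM, a ratio of 866 with a counting interval of 155 to 34200 (adjusted p = 2.36e-06). SPP1, the osteopontin gene, rose from 0.169 ± 0.239 to 633 ± 29.1 CPM (adjusted p = 5.82e-07). Their adjusted p without mdEM day 9 replicate 1 and 2 was 2.12e-06 and 2.31e-06 for SP7, and 2.04e-07 and 2.09e-07 for SPP1, whose log2 fold change was 11.78 and moved to 10.82 without replicate 2, while replicate 2 alone held 0 counts. BGLAP, the osteocalcin gene, fell from 24.8 ± 11.1 to 10.1 ± 1.25 CPM (adjusted p = 0.00981), a call lost without mdEM day 9 replicate 2 (adjusted p = 0.0546) and without day 38 replicate 1 (0.0912) or 2 (0.0513).

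Osteocyte genes rose in 10 of 11 cases and 0 fell, also adjusted over the list alone, with a median of 4.72, or 4.25 with genes at their bounds (adjusted p = 1.81e-07, adjusted p = 0.0737 with an estimated correlation). DMP1, a mineralisation protein gene of osteocytes and odontoblasts, had 0 counts at day 9 and 53.0 ± 6.75 CPM at day 38, at least 418-fold higher (adjusted p = 4.27e-06). SOST, the gene of the WNT inhibitor sclerostin, rose from 0.126 ± 0.178 to 119 ± 0.445 CPM, a ratio of 939 with a counting interval of 321 to 4560 (adjusted p = 1.88e-06). PHEX, an osteocyte endopeptidase gene of phosphate balance, rose from 0.168 ± 0.238 to 155 ± 2.32 CPM (adjusted p = 1.12e-06). SOST and PHEX had all their day 9 counts in mdEM day 9 replicate 2, without which their adjusted p was 5.48e-07 and 2.24e-07. Without mdEM day 9 replicate 1 it was 6.88e-07 and 4.09e-07. On chromosome 4 (GRCh38, GENCODE 29), DSPP at 87608553 to 87616910, DMP1 at 87650307 to 87664361, IBSP at 87799581 to 87812435, MEPE at 87821411 to 87846817 and SPP1 at 87975650 to 87983426 form a cluster of mineralised matrix genes.

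Dental mesenchyme and odontoblast genes rose in 11 of 13 cases and 1 fell, also adjusted over the list alone (median 4.53, adjusted p = 3.94e-06, adjusted p = 0.0768 with an estimated correlation). AMBN, the gene of the enamel matrix protein ameloblastin, on chromosome 4 at 70592256 to 70607288, had 2 counts at day 9 and 23010 ± 3911 CPM at day 38, a ratio of 273700 with a counting interval of 75800 to 2260000 (adjusted p = 9.83e-08). DSPP, whose products make up much of the noncollagenous dentin matrix, rose from 0.338 ± 0.240 to 6591 ± 1930 CPM, a log2 fold change of 14.21 (adjusted p = 1.65e-07). MMP20, the gene of an enamel protease, went from 0 counts to 829 ± 46.0 CPM, at least 6564-fold higher (adjusted p = 5.11e-07). Without mdEM day 9 replicate 1, which left DSPP 2 counts and AMBN 0, their adjusted p was 1.02e-07 and 2.1e-08. Without mdEM day 9 replicate 2 that of AMBN was 1.63e-08. The member that fell was BARX1, from 150 ± 12.7 to 4.50 ± 0.871 CPM (adjusted p = 2.17e-06).

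Collagen assembly and crosslinking genes rose in 23 of 28 cases, 1 fell and 4 did not pass (24 and 2 adjusted over the list alone, median 1.89, adjusted p = 2.09e-09, adjusted p = 0.0737 with an estimated correlation). LOX, the gene of a collagen crosslinking oxidase, rose from 0.591 ± 0.479 to 1971 ± 135 CPM, a log2 fold change of 11.68 (adjusted p = 1.65e-07) that was 11.03 without mdEM day 9 replicate 2. The adjusted p was 3.99e-08 without mdEM day 9 replicate 1, which left 3 counts. Tendon and ligament genes rose in 9 of 10 cases and 0 fell (9 and 1 adjusted over the list alone, median 4.31, adjusted p = 0.000126, adjusted p = 0.0867 with an estimated correlation). DCN, the gene of the collagen-binding proteoglycan decorin, rose from 36.4 ± 12.3 to 709 ± 38.0 CPM (adjusted p = 4.06e-06). COL14A1, a fibril-associated collagen gene, rose from 1.05 ± 0.183 to 121 ± 5.97 CPM (adjusted p = 4.53e-07). Chondrocyte genes rose in 10 of 17 cases and 5 fell (10 and 6 adjusted over the list alone, median 2.64, adjusted p = 0.0417, adjusted p = 0.324 with an estimated correlation), with an adjusted p of 0.0547 under size factors of the RLE type. COL10A1, a marker of hypertrophic cartilage, went from 0 counts to 6.54 ± 0.795 CPM, at least 51.6-fold higher (adjusted p = 0.000218). COL2A1 fell from 654 ± 35.6 to 336 ± 20.5 CPM (adjusted p = 0.00277), a call lost without day 38 replicate 2 (adjusted p = 0.06). ACAN, the gene of the cartilage proteoglycan aggrecan, stood at 0.0843 ± 0.000361 CPM at day 9 and 1.02 ± 0.178 CPM at day 38 (adjusted p = 0.0295), a call lost without mdEM day 9 replicate 1 (0.0843) or 2 (0.0903) and without day 38 replicate 1 (0.126) or 2 (0.0848).

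WNT response genes rose in 12 of 14 cases with 0 lower, also adjusted over the list alone (median 2.44, adjusted p = 2.62e-06, adjusted p = 0.0768 with an estimated correlation). APCDD1, a WNT inhibitor gene, rose from 13.2 ± 1.91 to 1473 ± 23.0 CPM (adjusted p = 1.81e-07). NOTUM, a WNT-inactivating enzyme gene, rose from 0.464 ± 0.0616 to 30.9 ± 5.02 CPM (adjusted p = 2.78e-06). Hedgehog response genes rose in 7 of 11 cases and 2 fell, also adjusted over the list alone (median 4.69, adjusted p = 0.00683, adjusted p = 0.133 with an estimated correlation). HHIP, a hedgehog-binding feedback gene, rose from 0.211 ± 0.0605 to 155 ± 5.54 CPM (adjusted p = 4.78e-07). FOXF1, a forkhead target of hedgehog signalling, rose from 0 counts to 44.0 ± 2.91 CPM, at least 347-fold higher (adjusted p = 5.13e-06). BMP response genes rose in 7 of 16 cases and 1 fell (8 and 1 adjusted over the list alone, median 0.89, adjusted p = 0.0362, adjusted p = 0.658 with an estimated correlation), and the list's adjusted p was 0.0747 without mdEM day 9 replicate 1. BAMBI, a pseudoreceptor gene, rose from 72.4 ± 19.9 to 897 ± 3.40 CPM (adjusted p = 9.81e-06). Glucocorticoid response genes rose in 8 of 13 cases and 2 fell (9 and 2 adjusted over the list alone, median 2.21, adjusted p = 0.00205, adjusted p = 0.114 with an estimated correlation). FKBP5, a glucocorticoid receptor cochaperone gene, rose from 73.1 ± 3.35 to 471 ± 35.8 CPM (adjusted p = 6.35e-06). The FGF response list, with 3 of 13 genes higher and 7 lower, did not pass (adjusted p = 0.218), and these counts were 1 and 4 without day 38 replicate 2.

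All 15 tested hypoxia response genes rose, also adjusted over the list alone (median 3.31, adjusted p = 5.49e-09, adjusted p = 0.0737 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase gene, rose from 3.12 ± 0.848 to 73.7 ± 8.27 CPM (adjusted p = 2.5e-06). P4HA1, which also serves collagen synthesis, rose from 17.9 ± 1.09 to 457 ± 8.70 CPM (adjusted p = 6.75e-07). Cell cycle genes fell in 23 of 24 cases with 0 higher (24 adjusted over the list alone, median -1.61, adjusted p = 8.48e-10, adjusted p = 0.181 with an estimated correlation). CENPF, a kinetochore gene, fell from 325 ± 0.695 to 69.6 ± 6.58 CPM (adjusted p = 1.71e-05). Ribosomal protein genes fell in 21 of 23 cases with 0 higher (22 adjusted over the list alone, median -1.03, adjusted p = 2.22e-07, adjusted p = 0.0947 with an estimated correlation), and in 12 without day 38 replicate 1. RPS3 fell from 3207 ± 8.42 to 1252 ± 49.2 CPM (adjusted p = 0.000213); reads of this family are uncertain because of its many processed pseudogenes. The list fell beside the rise in the share of counts held by the 10 most abundant genes.

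Pluripotency genes fell in 9 of 12 cases and 1 rose, also adjusted over the list alone (median -3.39, or -2.82 with genes at their bounds, adjusted p = 0.000276, adjusted p = 0.28 with an estimated correlation), and 5 fell without day 38 replicate 2. LIN28A fell from 610 ± 124 to 0.311 ± 0.299 CPM, a log2 fold change of -10.91 (adjusted p = 2.62e-07) that was -10.16 without day 38 replicate 2. Without day 38 replicate 1, which left 1 count, the adjusted p was 1.65e-06. SALL4, a zinc finger gene of pluripotent cells, fell from 98.4 ± 30.6 to 5.69 ± 1.11 CPM (adjusted p = 6.57e-06). IGDCC3, a cell surface immunoglobulin-domain gene, and NR6A1, an orphan nuclear receptor gene, were among the 8 largest falls, from 431 ± 9.36 to 9.86 ± 1.56 CPM (adjusted p = 3.65e-07) and from 42.7 ± 13.8 to 1.02 ± 0.0341 CPM (adjusted p = 5.05e-06). WFIKKN1, a gene of a secreted protease inhibitor, fell from 32.3 ± 12.7 CPM to 0 counts, at least 211-fold lower (adjusted p = 4.88e-05).

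Ectomesenchyme genes went both ways, with 6 of 18 higher and 7 lower (7 and 7 adjusted over the list alone); the median was -0.10 while the mean was 1.14, and the list did not pass (adjusted p = 0.852). TWIST1 fell from 398 ± 147 to 84.0 ± 6.99 CPM (adjusted p = 0.000169). DLX1 fell from 182 ± 26.5 to 33.9 ± 1.64 CPM (adjusted p = 4.58e-05), while MSX1 rose from 54.6 ± 14.4 to 216 ± 24.3 CPM (adjusted p = 0.000153). Mandibular patterning genes were also split, 6 higher and 6 lower of 14 (adjusted p = 0.731), and 2 higher and 5 or 4 lower without day 38 replicate 1 or 2. HAND2 fell from 473 ± 125 to 127 ± 8.14 CPM (adjusted p = 0.000223), and the fall of GSC from 45.5 ± 20.1 to 16.8 ± 1.57 CPM (adjusted p = 0.0047) lost its call without day 38 replicate 2 (adjusted p = 0.0538). The fall of DLX5 from 167 ± 48.3 to 92.8 ± 8.14 CPM (adjusted p = 0.0427) was lost without mdEM day 9 replicate 2 (0.191), day 38 replicate 1 (0.22) or day 38 replicate 2 (0.137). It was also lost under RLE size factors (log2 fold change -0.79) and the filter of 5 CPM (-0.81). The neural crest list had 2 of 18 genes higher and 7 lower (adjusted p = 0.0548), with 4 lower without either day 38 library and an adjusted p of 0.0453, 0.0447, 0.0181 and 0.039 without NCC aggregates day 5 replicates 1 and 2, mdEM day 9 replicate 2 and day 38 replicate 2. The adjusted p of that list was also 0.046 under RLE size factors, 0.0351 without the low-count filter and 0.0203 with fry. SOX10 fell further, from 28.5 ± 3.76 to 8.24 ± 1.93 CPM (adjusted p = 0.000587), and TFAP2A fell from 287 ± 56.2 to 89.2 ± 8.69 CPM (adjusted p = 0.000214).

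Epithelium genes rose in 10 of 13 cases with 0 lower (11 adjusted over the list alone, median 2.83, adjusted p = 2.62e-06, adjusted p = 0.225 with an estimated correlation). KRT5 and KRT17, keratin genes of basal epithelium, went from 0 counts to 42.5 ± 0.233 and 41.3 ± 0.707 CPM, at least 337- and 327-fold higher (adjusted p = 5.05e-06 and 5.26e-06); reads of KRT17 are uncertain because of near-identical copies. The maxillary and frontonasal list (2 higher and 5 lower of 12), the integrated stress list (4 and 4 of 11), the neural progenitor list (4 and 1 of 13), the neuron list (5 and 2 of 18) and the Schwann cell and glia list (3 and 3 of 10) did not pass (adjusted p = 0.216, 0.852, 0.535, 0.24 and 0.852). The median of the stress list was -0.53, its mean 0.18. Its counts were 2 and 3 without mdEM day 9 replicate 2 and 2 and 2 without day 38 replicate 2. The neuron counts were 10 and 1 without mdEM day 9 replicate 1 (adjusted p of the list 0.0228), 2 and 4 without mdEM day 9 replicate 2, and 2 and 1 without either day 38 library, and the glial counts were 5 and 2 without mdEM day 9 replicate 1.

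**Figure D2:**
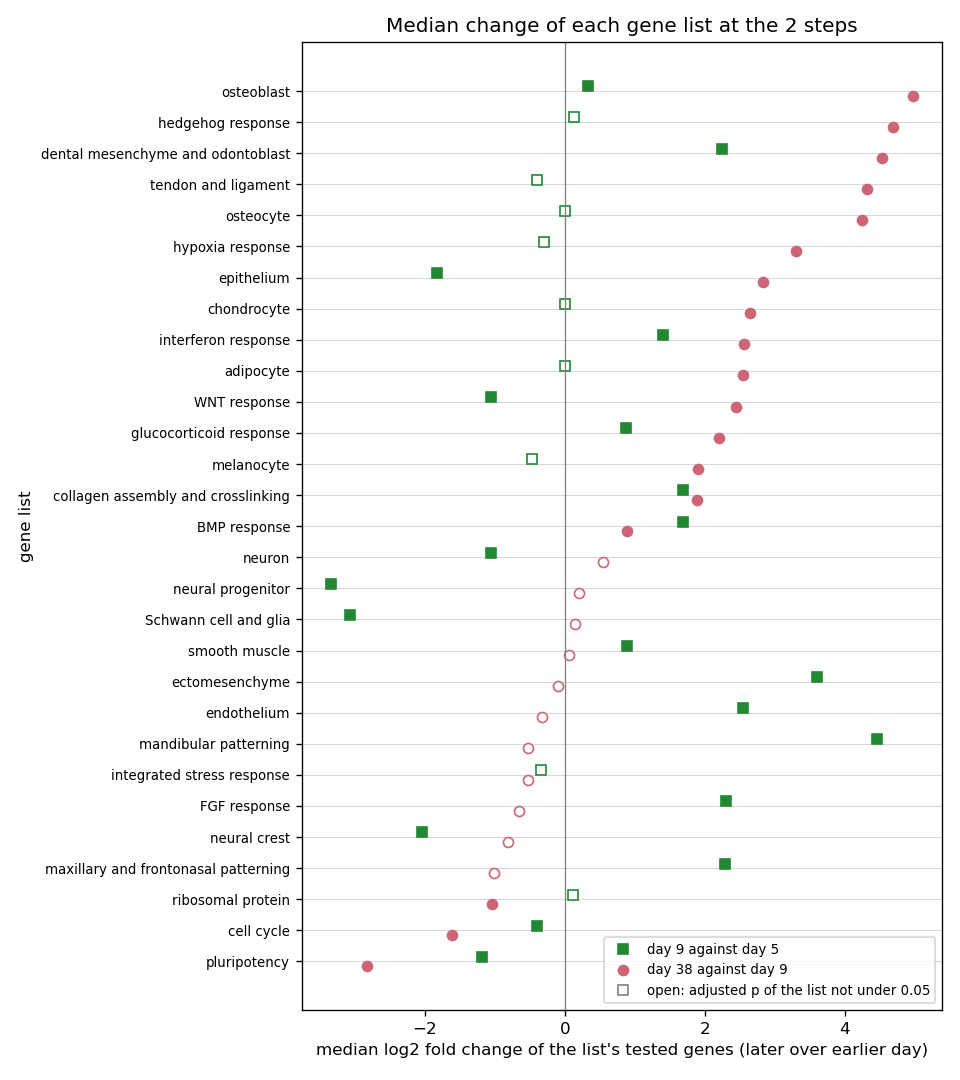
Median log2 fold change of the tested genes of 29 gene lists, with genes at 0 counts held at their bounds, for day 9 against day 5 (squares) and day 38 against day 9 (circles); filled symbols have a camera adjusted p under 0.05 at the preset correlation of 0.01. Mandibular patterning genes had a median of 4.47 at the first step, and osteoblast genes a median of 4.97 at the second.

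The third comparison spans the whole culture. From day 5 to day 38, 12 of 18 neural crest genes and 10 of 12 pluripotency genes fell, and 20 of 21 osteoblast genes rose. SOX10 fell from 586 ± 146 to 8.24 ± 1.93 CPM (adjusted p = 4.59e-07). EDNRA fell from 808 ± 212 to 133 ± 4.10 CPM (adjusted p = 2.15e-05). COL1A1 rose 6906-fold from 9.21 ± 0.281 CPM (adjusted p = 9.1e-09), and PANX3, a pannexin channel gene of osteoblasts and chondrocytes, went from 0 counts to 985 ± 4.94 CPM, at least 7695-fold higher (adjusted p = 2.14e-07). In all, 7328 genes (52.4%) changed, 4007 upward and 3321 downward, and 3369 and 2140 of these changed at least 2-fold. Without day 38 replicate 2 the number changed was 4831, and the number lower was 1893 and 1829 without day 38 replicates 1 and 2.

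Counts over the lists alone were the same where none are given below. Across this span 20 of 21 osteoblast genes rose and 0 fell (adjusted p = 1.29e-10, adjusted p = 0.0751 with an estimated correlation), as did 25 of 28 collagen assembly genes (26 and 1 lower adjusted over the list alone, adjusted p = 1.29e-10, adjusted p = 0.0751 with an estimated correlation). IFITM5, the gene of a bone-restricted membrane protein, went from 0 counts to 425 ± 20.0 CPM, at least 3315-fold higher (adjusted p = 2.14e-07). LOXL4, a lysyl oxidase-like gene, went from 0 counts to 95.9 ± 6.53 CPM, at least 749-fold higher (adjusted p = 6.9e-07). All 13 dental mesenchyme and odontoblast genes rose (adjusted p = 2.71e-08, adjusted p = 0.0894 with an estimated correlation), and so did 10 of 11 osteocyte genes, with 1 lower (adjusted p = 4.61e-05, adjusted p = 0.0987 with an estimated correlation). The dental list shares RUNX2 with the osteoblast list, DMP1 with the osteocyte list, and MSX1 with the ectomesenchyme and BMP response lists. It also shares BARX1, LHX6 and LHX8 with the mandibular list and PAX9 with the maxillary and frontonasal list. Ectomesenchyme genes were higher in 15 of 18 cases and lower in 1 (adjusted p = 1.3e-06, adjusted p = 0.186 with an estimated correlation), and mandibular patterning genes higher in 11 of 14 and lower in 0 (adjusted p = 0.000617, adjusted p = 0.241 with an estimated correlation). DLX4, a ventral arch homeobox gene, rose from 1.03 ± 0.305 to 83.4 ± 2.97 CPM (adjusted p = 1.77e-05). DLX2, at 42.8 ± 11.9 and 55.1 ± 7.18 CPM, did not differ beyond the spread (adjusted p = 0.221). The tendon list had 6 of 10 genes higher and 1 lower (7 and 2 adjusted over the list alone, adjusted p = 0.0133, adjusted p = 0.167 with an estimated correlation), and the chondrocyte list, at 9 and 4 of 17, did not pass (adjusted p = 0.119, but 0.0299 without NCC aggregates day 5 replicate 1 and 0.00238 with fry).

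Neural crest genes were lower in 12 of 18 cases and higher in 0 (adjusted p = 1.3e-06, adjusted p = 0.115 with an estimated correlation), and pluripotency genes lower in 10 of 12 and higher in 0 (adjusted p = 1.3e-06, adjusted p = 0.167 with an estimated correlation). L1TD1, an RNA-binding protein gene of pluripotent cells, fell from 108 ± 32.9 to 4.83 ± 0.919 CPM (adjusted p = 5.84e-06). KCNK5, a potassium channel gene, fell from 130 ± 8.50 to 0.662 ± 0.0499 CPM (adjusted p = 2.14e-07). The fall of NGFR from 155 ± 85.3 to 53.2 ± 0.308 CPM (adjusted p = 0.0264) was lost without NCC aggregates day 5 replicate 1 (adjusted p = 0.239) or either day 38 library (0.118), and also with DESeq2 (log2 fold change -1.51) and without the low-count filter (-1.55). All 24 cell cycle genes fell (adjusted p = 1.29e-10, adjusted p = 0.167 with an estimated correlation), as did 22 of 23 ribosomal protein genes (23 adjusted over the list alone, adjusted p = 1.35e-06, adjusted p = 0.115 with an estimated correlation), or 10 without day 38 replicate 1. Neural progenitor genes fell in 9 of 13 cases and 1 rose (adjusted p = 0.000854, adjusted p = 0.18 with an estimated correlation), and glial genes fell in 7 of 10 and 2 rose (adjusted p = 0.00627, adjusted p = 0.328 with an estimated correlation). The neural progenitor gene that rose was NES, an intermediate filament gene also found in mesenchyme, from 263 ± 32.2 to 863 ± 0.495 CPM (adjusted p = 0.000127).

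Among response lists, FGF genes were higher in 10 of 13 cases and lower in 0 (10 and 1 adjusted over the list alone, adjusted p = 0.0018, adjusted p = 0.115 with an estimated correlation), BMP genes in 11 of 16 (11 and 1; adjusted p = 0.00386, adjusted p = 0.393 with an estimated correlation) and hypoxia genes in 14 of 15 (adjusted p = 1.33e-06, adjusted p = 0.0987 with an estimated correlation). Hedgehog genes were higher in 8 of 11 cases and lower in 1 (adjusted p = 0.00386, adjusted p = 0.13 with an estimated correlation), and glucocorticoid genes higher in 10 of 13 and lower in 1 (adjusted p = 0.00186, adjusted p = 0.115 with an estimated correlation). ETV4, an ETS gene downstream of ERK, rose from 0.561 ± 0.215 to 20.6 ± 0.320 CPM (adjusted p = 3.2e-06). VEGFA, the angiogenic growth factor gene, rose from 4.24 ± 0.826 to 117 ± 11.9 CPM (adjusted p = 9.63e-07). The WNT list (9 higher and 4 lower of 14; 9 and 5 adjusted over the list alone), the maxillary and frontonasal list (7 and 3 of 12, 8 and 3 over the list alone; 4 and 3 without day 38 replicate 2), the neuron list (3 and 5 of 18; 2 and 3 without it) and the stress list (5 and 5 of 11) did not pass (adjusted p = 0.0756, 0.158, 0.468 and 0.804). The stress list had a median of 0.32 and a mean of 0.03 although its test leaned downward. Epithelium genes were higher in 5 of 13 cases and lower in 0 (adjusted p = 0.0273, adjusted p = 0.393 with an estimated correlation), with an adjusted p of 0.13 without NCC aggregates day 5 replicate 2.

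Some genes peaked or dipped at the mdEM stage. With a 2-fold change required at both steps, 340 genes were highest at day 9 and 322 lowest. The 2 steps share the day 9 libraries, so an error in them enters both steps with opposite sign and these counts stand without an expected value. Taking each step from a different day 9 library was not tried. Without day 38 replicate 2, 215 genes were highest at day 9. A rise at both steps was found for 450 genes and a fall at both for 79. GNAS, the gene of the stimulatory G protein subunit, went from 1.10 ± 0.415 to 85.4 ± 8.17 and back to 2.70 ± 0.126 CPM (adjusted p = 2.92e-06 and 1.59e-06 for the steps). The place in GNAS of the short stretch that the panel reads is not known. Any transcripts of GNAS without that stretch were not read, so these values need not be the level of the whole gene. CCBE1, a gene of lymphatic vessel growth, went from 1.06 ± 0.358 to 20.2 ± 0.331 and 1.57 ± 0.308 CPM (adjusted p = 3.77e-05 and 3.82e-05). ASS1, the gene of an arginine synthesis enzyme, dipped from 75.0 ± 16.9 to 7.04 ± 2.24 before 296 ± 12.4 CPM (adjusted p = 2.75e-05 and 1.36e-06). RELN, an extracellular matrix glycoprotein gene of neuronal migration, dipped from 88.6 ± 30.3 to 5.69 ± 0.680 before 122 ± 1.71 CPM (adjusted p = 1.47e-05 and 3.57e-06).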

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

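The crossed replicate block was chosen only after the result was seen; all other settings were fixed before. Named genes gave 5670 values on the same side of the threshold with the same sign, 124 weaker, 7 stronger and 0 reversed; lists gave 853 the same, 79 weaker, 24 stronger and 1 reversed, and 60 of the weaker came from the estimated correlation. With it, 0 lists changed in each comparison, in place of 20, 18 and 22, and the lowest adjusted p was 0.14, 0.0737 and 0.0751. The estimate was up to 0.553, for BMP response, but -0.00882 for the osteoblast list and 0.00746 for the hypoxia list. The latter 2 lie under the preset 0.01, so a higher correlation between genes does not account for the calls these lists lost. In the simulated data, whose genes were drawn independently, the raised list also went from camera adjusted p of 2.13e-19, 4.01e-21 and 6.77e-24 to 0.0795, 0.0508 and 0.0423. A call lost under the estimated correlation therefore does not by itself show correlated genes. With fry, which tests each list against no change and not against the other genes, the lists changed were 17, 24 and 27. The integrated stress list at day 38 against day 9, with no call in the main test (adjusted p = 0.852, leaning down), passed upward with fry (0.0173); the cause was not tested. At day 38 against day 9 fry also passed ectomesenchyme (0.0226) and smooth muscle (0.0121) upward, and maxillary and frontonasal (0.011) and FGF response (0.0123) downward. At day 38 against day 5 it passed maxillary and frontonasal (0.000813), melanocyte (0.000427) and WNT response (0.000222) upward. At day 9 against day 5 it passed melanocyte (0.0211) downward. DESeq2 called 3398, 5466 and 7027 genes in place of 3323, 5756 and 7328, and shared 3143, 5282 and 6937 with the same sign. The filter of 5 CPM left 2822, 4889 and 6165, with fewer genes tested, and fits of only the groups compared gave 2405, 5923 and 8043. Leaving out 1 library gave 2282 to 3566 genes at day 9 against day 5. For day 38 against day 9 it gave 3019 to 6108 changed, 1959 to 3304 higher and 1060 to 2839 lower, and for day 38 against day 5 4831 to 8281 changed and 1829 to 3834 lower. Genes highest at day 9 were 215 to 460. The lowest of the latter 6 ranges all came without clusters day 38 replicate 2, which leaves 1 library in that group, assumed to vary like the other groups. Other left-out libraries raised some of these counts; the cause was not tested. Without a fold limit, 492 genes were highest at day 9. Floors of 3 counts limit what can be said of genes under 0.313 CPM.

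The replicate numbers were also used as a replicate block, with 2 residual degrees of freedom, which gave 2576, 4876 and 6568 genes and 20, 18 and 22 lists, with 294 and 278 genes highest and lowest at day 9. The block also ended the call of DLX5 at day 38 against day 9 (log2 fold change -0.85). Replicate differences correlated across genes at -0.293 between day 5 and day 9 (-0.599 for genes over 32 CPM), at -0.00134 between day 5 and day 38 and at 0.00493 between day 9 and day 38, so samples of the same number did not deviate together, and those of day 5 and day 9 deviated in opposite directions, as crossed numbers could give. A crossed replicate block gave 3958, 6420 and 7892 genes; the cause was not tested.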

Other observations

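The bounds on keratin levels and core epithelial genes, and the use of the share of abundant genes, were chosen only after the result was seen.

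Interferon response genes rose at both steps, 5 of 12 with 0 lower at day 9 (also adjusted over the list alone, median 2.13, or 1.41 with genes at their bounds, adjusted p = 0.00228, adjusted p = 0.14 with an estimated correlation) and 7 with 0 lower at day 38 (8 over the list alone, median 2.56, adjusted p = 0.000111, adjusted p = 0.0867 with an estimated correlation). IFI6, an interferon-induced mitochondrial protein gene, went from 9.23 ± 1.83 to 28.2 ± 0.594 and 203 ± 2.95 CPM (adjusted p = 0.000492 and 6.74e-06). From day 5 to day 38, 10 of the 12 rose (adjusted p = 4.16e-05, adjusted p = 0.0987 with an estimated correlation). At day 9, smooth muscle genes rose in 6 of 13 cases with 0 lower (7 over the list alone, median 0.89, adjusted p = 0.00657, adjusted p = 0.19 with an estimated correlation), and in 3 without NCC aggregates day 5 replicate 2. ACTA2, the smooth muscle actin gene, rose from 8.48 ± 1.12 to 52.7 ± 17.2 CPM (adjusted p = 0.000164). From day 9 to day 38 the list had 4 higher and 3 lower (adjusted p = 0.731), and from day 5 to day 38 8 higher and 2 lower (adjusted p = 0.0219, adjusted p = 0.186 with an estimated correlation). MYL9, a myosin light chain gene, rose from 28.4 ± 3.70 to 385 ± 23.1 CPM between day 9 and day 38 (adjusted p = 1.43e-06). Endothelium genes rose in 7 of 8 cases at day 9 and 1 fell, also adjusted over the list alone (median 2.78, or 2.55 with genes at their bounds, adjusted p = 0.000941, adjusted p = 0.14 with an estimated correlation), with 4 higher without NCC aggregates day 5 replicate 2. That list did not pass from day 9 to day 38 (1 higher and 1 lower; adjusted p = 0.731). From day 5 to day 38 it had 6 higher and 2 lower (adjusted p = 0.08, but 0.0425 and 0.0431 without mdEM day 9 replicates 1 and 2 and 0.0301 and 0.0269 without day 38 replicates 1 and 2). It was also 0.0299 without the low-count filter and 0.0016 with fry.

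Melanocyte genes did not pass at day 9 (1 higher and 2 lower of 7; adjusted p = 0.335) and rose in 5 with 0 lower at day 38 (also over the list alone, median 1.90, adjusted p = 0.00454, adjusted p = 0.133 with an estimated correlation), or in 3 without day 38 replicate 1. GPNMB, a glycoprotein gene of melanosomes and also of osteoblasts, went from 1.10 ± 0.720 to 48.0 ± 1.18 CPM, a log2 fold change of 5.44 (adjusted p = 6.71e-06) that was 6.32 without mdEM day 9 replicate 1. From day 5 to day 38 that list had 4 higher and 3 lower (adjusted p = 0.306). Adipocyte genes did not pass at day 9 (adjusted p = 0.771) and rose in 3 of 6 with 0 lower at day 38 (also over the list alone, median 2.95, or 2.54 with genes at their bounds, adjusted p = 0.0141, adjusted p = 0.28 with an estimated correlation). The number was 5 without mdEM day 9 replicate 1, and the adjusted p of the list was 0.0716 without mdEM day 9 replicate 2 and 0.111 without the low-count filter. From day 5 to day 38 4 rose (adjusted p = 0.0328, adjusted p = 0.288 with an estimated correlation), with 0.0599 without NCC aggregates day 5 replicate 2 and 0.0944 without the filter. CD36, a fatty acid transporter gene, rose from 2.23 ± 0.408 to 78.2 ± 7.76 CPM between day 9 and day 38 (adjusted p = 6.24e-06). Epithelium genes fell at day 9 in 6 of 13 cases with 0 higher (7 over the list alone, median -1.83, adjusted p = 0.000723, adjusted p = 0.321 with an estimated correlation), or in 3 without NCC aggregates day 5 replicate 1, and the list's adjusted p was 0.0523 with fry. Too few striated muscle genes (summed level 46.3, 48.4 and 20.6 CPM at the 3 stages) and blood and osteoclast genes (10.7, 26.5 and 27.4 CPM) passed the filter for a test. CTSK, the osteoclast protease gene also found in fibroblasts, rose from 5.44 ± 0.511 to 20.7 ± 4.32 CPM at day 9 (adjusted p = 0.000679).

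AMBN, MMP20 and DSPP were among the largest rises at day 38, and enamel-forming epithelial cells were weighed as a candidate explanation. Such cells would be likely to hold AMELX, the main enamel matrix transcript, at 0.1 or more of the AMBN level, a bound written before. The ratio was 0.000569 on average and 0.000624 at most, with AMELX at 12.9 ± 0.432 CPM, which argues against those cells as the main source of the AMBN reads. Levels of different genes also depend on their primers. Expression in osteogenic or odontoblast-like cells could not be set apart from this bulk measurement.

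The rise of epithelial genes at day 38 might come from epithelial cells in the clusters. Of 8 core epithelial genes, 1 rose with 5 CPM or more and 4 rose at any level, while 6 keratins of the list rose to a median of 36.7 CPM. The count of 1 lay within the bound set against epithelial cells. A verdict against them also required a much higher keratin median, which was not reached. The test therefore cannot tell, since a small share of epithelial cells could give keratins at that level and core genes under 5 CPM. No other biological explanation was tested.

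The fall of ribosomal protein genes at day 38 could follow from a few genes, collagens foremost, taking many counts. Scaling without the 100 most abundant genes gave a median log2 fold change of -1.03 with an upper quartile of -0.756 over 23 genes. That setting moved the median of all genes by only 0.004, so by itself it tests little. From day 9 to day 38 the share of the 10 most abundant genes gave the other genes a shift of -0.217 in log2 if left uncorrected. That is not a maximum, because each library has its own 10 genes. At day 38 those genes held 20.8 and 21.0% of the counts. Even had they held none at day 9, that share would give a far smaller fall than -1.03 in log2. These values argue against the 10 most abundant genes as the cause of most of the fall. No biological explanation was tested.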
